A study of Mus musculus with 8 samples.

How the data were processed

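Single-cell RNA was measured in pancreatic ductal adenocarcinomas of 8 KPC mice, a genetically engineered model of this cancer. Per the labels' protocols, palpable tumours were digested with collagenase, tumour cells were enriched by magnetic sorting, and libraries were made with 10x Chromium version 2 chemistry, which tags each transcript with a unique molecular identifier (UMI). The deposited matrices hold raw UMI counts per gene and barcode, 1 matrix per tumour, made with Cell Ranger 2.1.1 and the mouse build GRCm38 (mm10), per the submitters' processing notes. The same notes name Seurat 2. Deposited tables of cancer cells give each cell's library, cluster number, trajectory state number, UMI count, mitochondrial share (a fraction in the deposited table, printed here as a percent) and pseudotime, a unitless score that the deposited header attributes to Monocle. Parameters of these steps, and the version of Monocle, are not given in the sources used here.

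The 8 samples form 1 group, KPC tumor, and are called tumours 1 to 8 in accession order. Each is a separate mouse, so the mouse is the replicate throughout and cells are not. The deposited library names carry the prefix CT01 for tumours 1 to 4 and CT02 for tumours 5 to 8, treated here as 2 batches. The deposited sample and batch columns were not used. The sample column names another library than the cell's own library name for 17465 of 23991 cells (72.8%), and 17380 of these barcodes do not occur in the library that it names. The batch column differs from the prefix of the cell's own library name for 12807 cells. By library name, all 23991 barcodes were found in their matrix and 23987 had a UMI total within 1% of the deposited one. A further 17 columns of per-cell values were left unused. The cancer cells have at least 500 detected genes and at most 15.0% mitochondrial UMIs (largest value 14.992%), and 1030 of them have no state number. These 1030 stay in the comparison arm of each state contrast. No cell was removed by any other filter here. The 28692 features hold 67 duplicated symbols, which were told apart by identifier.

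For each deposited state, UMI counts were summed per tumour over the state's cells and over all other cancer cells of the same tumour. A tumour entered when both sums held at least 20 cells, and a state was tested when at least 4 tumours entered, which left 8 of 13 states. The sums were compared with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM normalization, the default expression filter and the tumour as a block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in size. All per-gene adjusted p-values below are from this edgeR test and are two-sided, and errors of log2 fold changes are standard errors. The states and the pseudotime were derived by the authors from these same expression values, so the contrasts describe the states and are not independent evidence that they exist. Contrasts between cancer cells and other annotated classes were planned and not run, because the deposited annotation holds cancer cells only.

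The 29 gene lists, the markers of 14 cell types, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 224 tests of lists and states, and again with an estimated correlation. Camera asks whether a list's genes rank apart from other genes. Differences of a list between batches were tested on its mean difference per tumour in log2(CPM + 10), with an exact two-sided permutation of the batch labels adjusted over the lists of a state, a test chosen after the data had been examined. The named genes of a state are up to 4 called members of each list past its threshold, the 5 largest rises and 5 largest falls at an average log2 CPM of at least 5 that went the same way in every tumour (leaving out unnamed gene models, ribosomal protein and mitochondrial genes), and Trp53, Pdx1, Cdkn2a and Myc, with 1 further gene that is not reported here. Gene positions are those of GENCODE vM21 on GRCm38.

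Along pseudotime, cancer cells were divided into 5 bins of equal cell number over all tumours. A list's level in a bin was the mean over members of log2(CPM + 10) of the summed counts. The slope of level on bin number was taken within each tumour that had at least 20 cells in at least 3 bins, and the slopes of 7 tumours were tested with an exact two-sided sign-flip permutation test adjusted over 29 lists. The smallest p this design allows is 0.0156. Of 10 planned relations across tumours, 9 were computed, with exact two-sided pairing permutation tests, and again with each batch's mean taken out of the levels and 576 pairings permuted within batches. The relation with macrophage share was not, because no macrophage-like cluster was found. The spread between tumours was the SD of log2 CPM of summed cancer cells, for 9112 genes with a CPM of at least 10 in at least 1 tumour and a prior of 0.5 counts.

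The 5076 barcodes outside the annotation were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5) into 14 clusters. A cluster took a cell-type name when at least 3 of that type's fixed markers were each found in at least 20% of its cells at a mean at least 4 times that of all other barcodes, with 10 CPM added to both means, and when no other type had more markers among its top 10 genes. Where several types had such markers, the name is that of the type with the largest share of its markers. This naming rule, the prior of 0.5 counts, the expression filters of the batch and length comparisons, the minimum of 3 bins when 10 bins were used and the UMI window of the depth comparison were set after the data had been examined, at 1 setting each. Scrublet marked 37 of 29067 barcodes (0.127%), too few to have worked at this loading, so no doublets were removed. Of the unannotated barcodes, 1569 fall below the 500 genes or above the 15% mitochondrial share that bound the cancer cells.

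The edgeR contrasts of the states and the slope test were checked on simulated counts drawn from the real means and library sizes, each with 200 changed genes. The changed genes were drawn only from genes of higher counts, so recovery among genes of low count was not measured. Camera, the interaction tests and the other permutation tests were not checked in this way. The edgeR step recovered 87 to 95% of genes changed by a log2 fold of 2.5 and 54 to 96% of those changed by 1.5, depending on the state, and called 1 to 12 unchanged genes. The slope test called 10 of 10 lists of genes given a slope of 0.5 in size and 0 of 19 unchanged lists. The changed lists were recovered at a mean size of 0.369, above most of the list slopes below. Unchanged genes were simulated with no slope, whereas the median gene slope in the real counts was 0.183. The 0 of 19 therefore does not cover a shift shared by many genes. Total UMI counts per tumour ran from 18625354 to 59332005. Alternatives tried were other normalization, DESeq2 1.42.0, no expression filter, no block, other cell minimums, no fold minimum, a joint fit of all states, sums thinned to equal totals, filters on Ptprc-positive and mitochondrial-rich cells, fry, other bins, pseudocounts and averages, and each tumour left out in turn. The joint fit set a state against the mean of the other states at equal weight, over sums of at least 20 cells. States held mostly by other tumours entered that mean, and cells without a state did not. It is therefore another contrast than that with the other cancer cells of the same tumours. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the remaining steps.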

Results

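Single-cell transcriptomes were collected from pancreatic tumours of 8 KPC mice to follow how the transcriptional states of the cancer cells are arranged during progression. The 8 matrices held 29067 barcodes (3633 ± 732 per tumour, SD, n = 8), of which 23991 carried the deposited cancer cell annotation (2999 ± 783 per tumour). Sequencing depth ranged from 18625354 UMIs in tumour 5 to 59332005 in tumour 1. Cancer cells of tumour 5 had a median of 4361 UMIs and 1419 genes, against 13188 UMIs and 3462 genes in tumour 1. The number of molecules behind a value therefore differed between tumours and between states. Over the 8 states tested below, the sum of a state's cells in a tumour ran from 170205 UMIs (state 1 in tumour 1) to about 24519700 (state 12 in tumour 2).

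Annotated cancer cells made up 82.7% ± 13.7 of barcodes (SD, n = 8), from 52.4% in tumour 5 (95% exact binomial interval 50.8 to 54.0%) to 97.8% in tumour 3. The other barcodes included acinar-like cells with digestive enzyme genes such as Cpa1 and Ctrb1 (2.63% ± 4.46), mesothelial-like cells with Upk3b, Lrrn4 and Wt1 (4.83% ± 8.30), fibroblast-like cells with collagen genes and Dcn (3.45% ± 3.63), and endocrine-like cells with the insulin genes Ins1 and Ins2 (0.242% ± 0.205). A further 6.12% ± 2.71 of barcodes fell in clusters with no name. Those of 519, 328, 318 and 227 barcodes had median mitochondrial shares of 15.8 to 18.8%, and that of 57 had 90.9%. The unnamed clusters of 336 and 41 barcodes had 1.97% and 4.91%. Mesothelial-like cells reached 25.1% in tumour 5 and were 4.11% or less elsewhere. Of the 941 in tumour 5, 937 lay in a cluster with Wt1 in 49.4% and Upk3b in 31.3% of barcodes but also Dcn in 97.4%. For this cluster 4 mesothelial and 4 fibroblast markers passed the naming rule. A cluster of 336 barcodes, 285 of them from tumour 5, had Wt1 in 54.2%, Upk3b in 28.3% and Dcn in 92.0% and took no name. Acinar-like cells reached 13.3% in tumour 6 and were 3.89% or less in each other tumour. Endocrine-like cells were found in 0 of 3200 barcodes of tumour 3, which by a limit of 3 counts allows a share of up to 0.0938%, and in 0 of 2606 barcodes of tumour 7, which allows up to 0.115%. These intervals and limits cover counting error only, and the shares are those after magnetic enrichment of tumour cells. No cluster carried the markers of macrophages, neutrophils, T, B, dendritic, endothelial, pericyte, erythroid or Schwann cells by the rule used. Ptprc, the pan-leukocyte gene CD45, was detected in 68 of 23991 annotated cancer cells and in 14 of 5076 other barcodes.

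**Figure D1:**
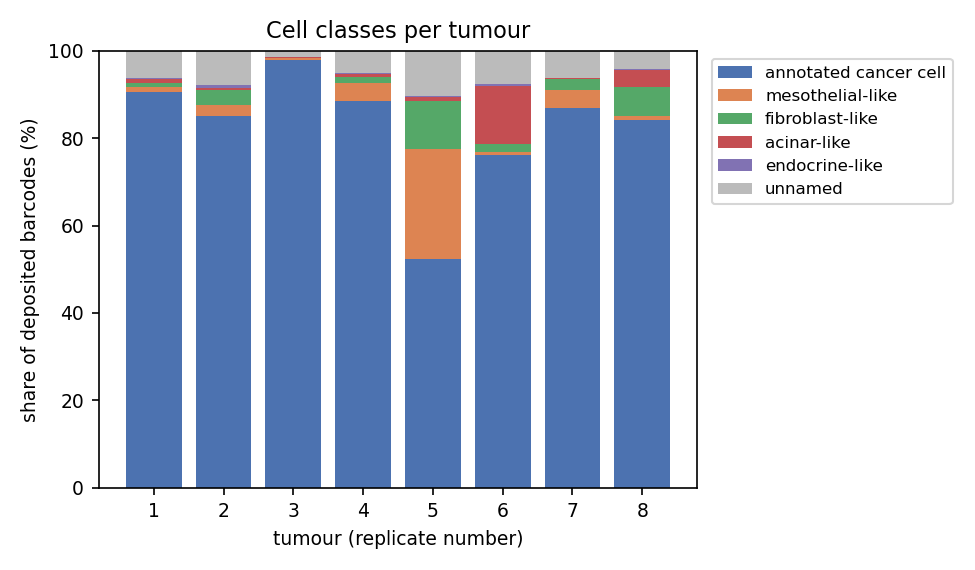
Percent of barcodes (y axis) in each cell class for each of the 8 tumours (x axis). Tumour 5 has the lowest share of annotated cancer cells (52.4%) and the highest of mesothelial-like cells (25.1%), and tumour 6 the highest of acinar-like cells (13.3%).

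Transcripts typical of other cell types were detected at low level in the cancer cells. Ctrb1, a chymotrypsinogen of acinar cells, had at least 1 UMI in 67.1% of cancer cells at a mean of 322 CPM, against 100% and 172515 CPM in acinar-like cells, with median depths of 9238 and 4651 UMIs. Col3a1, a fibrillar collagen, was found in 15.7% of cancer cells and 97.54% of fibroblast-like cells, whose median depth was 4276 UMIs. Whether they came from free RNA or from the cancer cells themselves was not tested, and low values of acinar, endocrine and collagen genes are not read as expression.

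The deposited annotation divided the cancer cells into 13 trajectory states and 6 clusters, and the tumours were unequally spread over both. Cluster 3 came to 99.9% from tumour 1, cluster 4 to 99.5% from tumour 6 and cluster 5 to 99.8% from tumour 7. The larger clusters 0, 1 and 2 were mixed, with 50.4% from tumour 4, 69.7% from tumour 2 and 41.4% from tumour 8 as their highest shares. Median pseudotime lay at 50.9, 24.6, 43.5 and 33.9 in tumours 1 to 4 and at 8.79, 8.65, 1.93 and 9.37 in tumours 5 to 8, so that the 4 tumours of batch CT01 were all above the 4 of batch CT02. With 1 batch on each side, the batch and differences between these mice cannot be told apart. State 4 was the only one of the 13 with at least 20 cells in all 8 tumours, with 27.8% from tumour 8 as its highest share, whereas batch CT01 supplied 2.61% of state 1, 2.33% of state 13, 89.5% of state 12 and 98.0% of state 8. Each of 8 states was compared with the other cancer cells of the same tumours, which asks what sets the cells of a state apart from the rest of the tumour they came from. All gene calls rest on this comparison within tumours: without the tumour as a block the genes called were 140 in state 12, 1 in state 3 and 0 in states 1, 4, 7 and 13.

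**Figure D2:**
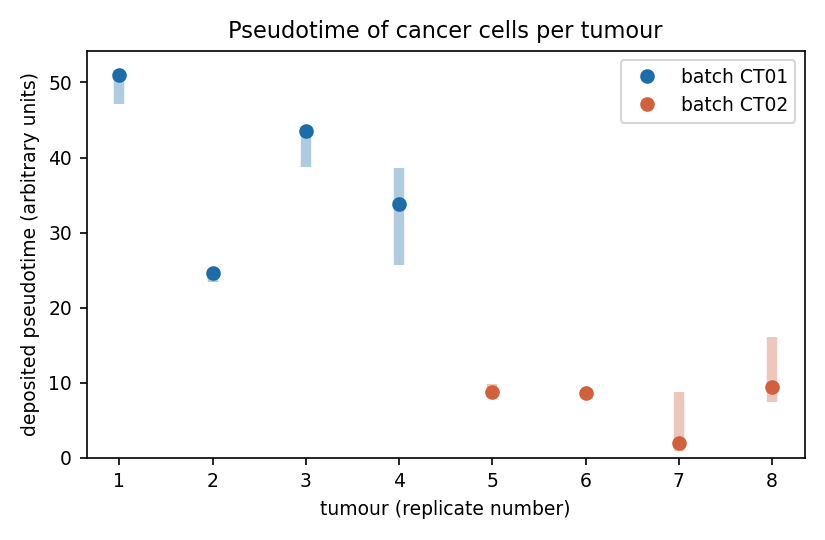
Deposited Monocle pseudotime (y axis, no unit) of the cancer cells of each tumour (x axis), as the median with a bar from the lower to the upper quartile, coloured by batch. Medians run from 24.6 to 50.9 in batch CT01 and from 1.93 to 9.37 in batch CT02.

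State 12 held 3125 cells at a median pseudotime of 24.6 and was compared with the other cancer cells of 5 tumours (1, 2, 4, 7 and 8). It was marked by epithelial and gastric-type genes and by low mesenchymal genes. Of 12835 genes tested, 833 rose and 807 fell. By the rule for named genes, the largest rises were Lypd8 (log2 fold change 4.54 ± 0.69, adjusted p = 0.0114), a flagellin-binding protein of the gut surface, Pigr (4.23 ± 0.60), the receptor that carries polymeric immunoglobulin across epithelia, Tff3 (4.003 ± 0.66), a trefoil factor of goblet cells, Clca1 (3.78 ± 0.64) and the sulfotransferase Sult1d1 (3.64 ± 0.78). The largest falls were Inhba, the activin A subunit (-5.38 ± 0.52, adjusted p = 0.00217), Ankrd1 (-4.37 ± 0.42), the antioxidant Gpx8 (-4.17 ± 0.76), the intermediate filament Vim (-4.16 ± 0.49) and the galectin Lgals1 (-3.95 ± 0.54). Each of these genes moved the same way in all 5 tumours.

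By list, 18 of 25 measured classical and gastric-type genes rose in state 12 and 0 fell (20 when adjusted over the list alone), among them Spink4 (3.17 ± 0.50), Muc6 (3.14 ± 0.62), a gastric gland mucin, and Vsig2 (3.01 ± 0.70). The list's adjusted p was 1.38e-14 at the preset correlation, and adjusted p = 0.464 with an estimated correlation. Epithelial junction genes rose in 11 of 22 (17 over the list alone), with Ovol1, a repressor of mesenchymal genes, at 3.12 ± 0.58 and the tight junction gene Ocln at 2.20 ± 0.48 (list adjusted p = 5.88e-09; adjusted p = 0.554 with an estimated correlation). All 5 measured transcription factors of epithelial-mesenchymal transition fell, including Twist1 (-3.42 ± 0.50), Zeb1 (-3.23 ± 0.31), Snai2 (-3.03 ± 0.87) and Zeb2 (-2.96 ± 0.50), as did 8 of 14 mesenchymal adhesion genes (10 over the list alone) such as N-cadherin Cdh2 (-3.84 ± 0.48) and the kinase receptor Axl (-3.69 ± 0.32). Both lists passed at the preset correlation (adjusted p = 4.49e-06 and 4.54e-12) and each had adjusted p = 0.237 with an estimated correlation. Matrix genes fell in 7 of 20 (8 over the list alone), with tenascin Tnc at -3.88 ± 0.36 and fibronectin Fn1 at -3.44 ± 0.27, and 7 of 20 targets of YAP and TEAD fell (8 over the list alone), with Ctgf at -1.81 ± 0.27. These had adjusted p = 0.464 and adjusted p = 0.482 with an estimated correlation. Cell cycle genes fell as well, 19 of 24 for G2/M (23 over the list alone; Ube2c -1.98 ± 0.39) and 11 of 22 for S phase (12 over the list alone; Rrm2 -1.77 ± 0.40), again with adjusted p = 0.464 and adjusted p = 0.482 with an estimated correlation. Of the smaller lists, 3 of 16 genes of MHC class I presentation rose (5 over the list alone), among them H2-D1 (1.37 ± 0.36), whose reads can be shared with near-identical class I genes, and 4 of 19 TGF-beta response genes fell (5 over the list alone). Their adjusted p with an estimated correlation was 0.645 and 0.487. The immediate early list was divided, with 4 of 22 genes up, including the heat shock gene Hspa1b (1.78 ± 0.32), and 3 down, including Klf2 (-1.79 ± 0.30), 7 in all over the list alone (adjusted p = 0.645 with an estimated correlation). Of the genes named in advance for every state, Cdkn2a (-1.71 ± 0.50) and Myc (-1.28 ± 0.29) fell, Trp53 (-0.79 ± 0.19) passed on p but not on size, and Pdx1 was 0.09 ± 0.23.

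Vim lies on chromosome 2 (13573927 to 13582826, plus strand, ENSMUSG00000026728), Zeb1 on chromosome 18 (5591860 to 5775467, plus strand, ENSMUSG00000024238), and Inhba on chromosome 13 (16011851 to 16031621, plus strand, ENSMUSG00000041324), all protein-coding genes in GRCm38. The count of state 12 rested on its 5 tumours: 301 genes were called without tumour 4, 235 without tumour 7 and 170 without tumour 8, 35 in batch CT01 alone and 0 in batch CT02 alone, where 2 tumours entered. Tumour 2 supplied 70.02% of the state's cells, and the count was 1042 on sums thinned to equal totals.

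**Figure D3:**
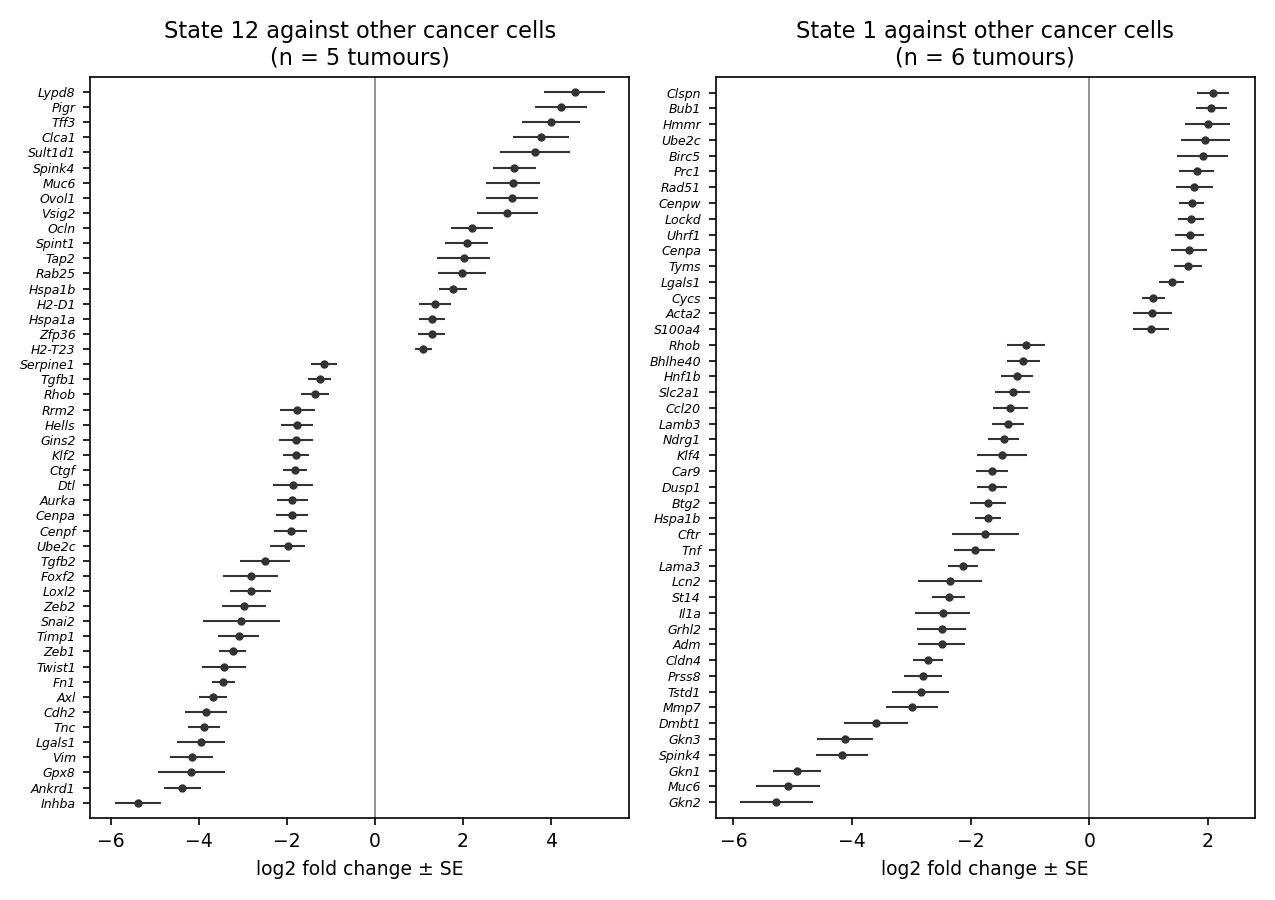
Log2 fold change (x axis) of the named genes of states 12 and 1 against the other cancer cells of the same tumours, with bars of 1 standard error (5 tumours for state 12, 6 for state 1). In state 12 Lypd8 lies at 4.54 and Inhba at -5.38, and in state 1 Clspn lies at 2.09 and Gkn2 at -5.28.

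State 4, with 2677 cells at a median pseudotime of 15.9, was compared in all 8 tumours. It carried 177 higher and 89 lower genes among 11206 tested. Gastrokines Gkn1 (3.599 ± 0.74, adjusted p = 0.0300) and Gkn2 (3.497 ± 0.71, adjusted p = 0.0289), secreted proteins of the gastric mucosa, rose together with Vsig2 (2.14 ± 0.31), the mitochondrial creatine kinase Ckmt1 (2.12 ± 0.32), the dual oxidase maturation factor Duoxa2 (2.097 ± 0.26) and the mucin Muc5ac (2.19 ± 0.46, in 7 of 8 tumours). Inhba fell (-2.39 ± 0.26, adjusted p = 0.000807), as did the kinase Prkg2 (-1.55 ± 0.19), Dpysl3 (-1.42 ± 0.26) and Ggct (-1.27 ± 0.20). Gkn1 and Gkn2 are neighbours on chromosome 6, at 87345650 to 87350942 and 87373357 to 87379497, followed by Gkn3 at 87383256 to 87388935.

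Of the lists, 6 of 24 classical and gastric-type genes rose in state 4 (13 when adjusted over the list alone) and 6 of 22 epithelial junction genes rose (11 over the list alone), for example the trafficking GTPase Rab25 (1.77 ± 0.32) and the transcription factor Elf3 (1.24 ± 0.21). These 2 lists had adjusted p = 0.237 and adjusted p = 0.332 with an estimated correlation, against 1.88e-19 and 4.12e-17 at the preset one. Mesenchymal adhesion genes fell in 5 of 12 (6 over the list alone), with Cdh2 at -1.48 ± 0.26 and Vim at -1.25 ± 0.32, and 2 of 3 measured transition factors fell, Zeb2 (-1.67 ± 0.28) and Twist1 (-1.39 ± 0.32). Both had adjusted p = 0.237 with an estimated correlation. G2/M genes fell in 3 of 24 (10 over the list alone; Hmmr -1.55 ± 0.26), with adjusted p = 0.464 with an estimated correlation. Taken per tumour in log2(CPM + 10), their mean difference from the other cancer cells was -0.38 ± 0.83 in batch CT01 and -0.86 ± 0.41 in batch CT02 (SD, n = 4 each). This gap between batches did not pass (exact two-sided permutation p = 0.343, adjusted p = 0.565). Mitochondrially encoded genes, a sign of RNA quality, and acinar genes also ranked higher, with means of 0.47 and 0.36 and 0 members called. Their adjusted p was 3.03e-05 and 0.0185 at the preset correlation, and adjusted p = 0.560 and adjusted p = 0.723 with an estimated correlation. Per tumour, mitochondrially encoded genes stood at 0.88 ± 0.23 in batch CT01 and 0.0090 ± 0.31 in batch CT02 (exact permutation p = 0.0286, the smallest that 70 splits allow, adjusted p = 0.114). Acinar genes stood at 0.64 ± 0.63 and -0.11 ± 0.41 (exact permutation p = 0.0857, adjusted p = 0.218). Of 11 basal-like genes, 2 rose (3 over the list alone), the squamous and stress gene Sfn (1.26 ± 0.27) and S100a14 (1.28 ± 0.28), with adjusted p = 0.441 with an estimated correlation. The count fell to 162 without tumour 3, to 106 without tumour 7 and to 156 without tumour 8. It was 580 in the joint fit of all states, 204 in batch CT01 and 560 in batch CT02, and 549 genes differed between the batches by an interaction test, with r = 0.233 across genes, which are not independent replicates, between the batches' fold changes.

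State 1 lay at the start of pseudotime (2946 cells, median 2.06) and was compared in 6 tumours. Genes of cell division rose, among them Clspn (2.09 ± 0.27, adjusted p = 4.46e-05), a replication checkpoint adaptor, the spindle checkpoint kinase Bub1 (2.05 ± 0.26), the spindle protein Hmmr (2.00 ± 0.38), the mitotic ubiquitin ligase component Ube2c (1.96 ± 0.41) and Birc5 (1.91 ± 0.43), or survivin. Genes of the classical and gastric-type list fell by large factors, with Gkn2 at -5.28 ± 0.61 (adjusted p = 0.000406), Muc6 at -5.08 ± 0.54, Gkn1 at -4.93 ± 0.40, Spink4 at -4.18 ± 0.44 and Gkn3 at -4.12 ± 0.47. In all, 364 genes rose and 922 fell of 11075 tested.

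In state 1, 23 of 24 G2/M genes and 14 of 22 S phase genes rose (23 and 14 over the list alone), and each list had adjusted p = 0.464 with an estimated correlation. Falls covered 15 of 21 epithelial junction genes (15 over the list alone), including the serine protease Prss8 (-2.81 ± 0.32) and claudin Cldn4 (-2.72 ± 0.26), 14 of 24 classical genes (15 over the list alone), and 11 of 22 immediate early genes (14 over the list alone), such as Hspa1b (-1.71 ± 0.23) and Dusp1 (-1.65 ± 0.25). Their adjusted p with an estimated correlation was 0.483, 0.464 and 0.464. Hypoxia genes fell in 10 of 21 (10 over the list alone), with adrenomedullin Adm at -2.49 ± 0.40 and carbonic anhydrase Car9 at -1.64 ± 0.27, ductal genes in 5 of 11 (6 over the list alone), with Mmp7 at -2.99 ± 0.44, and tumour cytokine genes in 4 of 23 (4 over the list alone), with Il1a at -2.47 ± 0.46. Their adjusted p with an estimated correlation was 0.464, 0.464 and 0.386. Of the laminin and integrin list, 2 of 14 fell (2 over the list alone), among them Lama3 (-2.13 ± 0.25), and of the mesenchymal list 3 of 12 rose (3 over the list alone), including Lgals1 (1.39 ± 0.21), with adjusted p = 0.464 and adjusted p = 0.491 with an estimated correlation. Myc (0.14 ± 0.24) did not pass. The 6 tumours were not alike: 472 genes differed between batches by an interaction test. Taken per tumour in log2(CPM + 10), the mean difference of G2/M genes was 0.068 ± 0.80 in 2 tumours of batch CT01, where the state held 22 cells of tumour 1 and 33 of tumour 3, and 1.37 ± 0.40 in 4 of batch CT02 (SD). S phase genes stood at 0.10 ± 0.50 and 0.79 ± 0.12, immediate early genes at -2.40 ± 0.62 and -0.59 ± 0.24, and mitochondrially encoded genes, a sign of RNA quality, at 0.79 ± 0.36 and -0.34 ± 0.22. Each of these gaps between batches had an exact two-sided permutation p of 0.0667 (adjusted p = 0.129), the smallest that 15 splits allow, so this permutation test cannot pass the threshold.

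G2/M genes fell in states 13, 3 and 7, in 24, 7 and 11 of 24, against a comparison arm that held state 1. State 1 made up 15.2 to 69.9% of the cells with a state in tumours 5 to 8. In those tumours the falls were therefore not measured apart from its rise. In tumours 1 to 4, state 1 made up only 0.244 to 1.09% of these cells. There the G2/M genes of state 7 still stood at -0.75 ± 0.28 per tumour in log2(CPM + 10) (SD, n = 4). Of these 4 tumours only tumour 2 entered for state 13, and none for state 3. The joint fit of all states sets a state against the equally weighted mean of the other states, state 1 among them. A call lost there is a call lost in another contrast. In the joint fit, 6 named genes of state 13 kept their call, 9 lost it and 3 turned. In that fit 0 kept it and 21 lost it in state 3, and 5 kept it and 5 lost it in state 7. In state 13 (3263 cells, median pseudotime 8.67, 5 tumours) 27 genes rose and 196 fell of 10887. All 24 G2/M genes fell, led by cyclin Ccna2 (-3.31 ± 0.35, adjusted p = 1.57e-06), Hmmr (-3.17 ± 0.31), the kinase Aurkb (-3.05 ± 0.40) and Ube2c (-2.97 ± 0.26), and so did 10 of 22 S phase genes (12 over the list alone; Clspn -2.45 ± 0.29), with adjusted p = 0.237 and adjusted p = 0.332 with an estimated correlation. Mitochondrially encoded genes, a sign of RNA quality, and acinar genes ranked higher in state 13, with means of 0.67 and 0.61 and 0 members called (1 and 0 over the list alone). Their adjusted p was 9.68e-13 and 1.11e-10 at the preset correlation, and adjusted p = 0.441 and adjusted p = 0.332 with an estimated correlation. Of its cells 52.9% came from tumour 6, where acinar-like cells were most frequent, though both arms came from the same tumours. The median depth of state 13 cells was 4864 UMIs, the lowest of the 8 states tested. Whether depth or free RNA set these ranks was not tested. Hist1h2ap, a histone gene with near-identical copies between which reads can be shared, was at -3.11 ± 0.25. The copper carrier ceruloplasmin Cp rose (1.20 ± 0.27), as did the long noncoding RNA AW112010 (1.03 ± 0.22) and the hypoxia gene Bnip3 (1.07 ± 0.26, in 4 of 5 tumours). Muc6 (-2.02 ± 0.34) and Gkn3 (-1.37 ± 0.24) fell, within 3 of 24 classical genes that did (5 over the list alone; adjusted p = 0.564 with an estimated correlation). In the joint fit of all states, which called 471 genes, their estimates turned to 0.78 and 1.36 and did not pass (adjusted p = 0.720 and 0.110).

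State 3 (325 cells, median pseudotime 8.92, tumours 5 to 8) had lower classical and gastric-type genes and higher hypoxia genes. Gkn3 (-5.87 ± 0.35, adjusted p = 3.65e-11), Gkn2 (-5.59 ± 0.37), Muc6 (-5.53 ± 0.87), Gkn1 (-5.22 ± 0.29) and the disulfide isomerase Agr2 (-4.85 ± 0.34) fell, within 10 of 24 classical genes that did (12 over the list alone; adjusted p = 0.237 with an estimated correlation). The secreted protein Prap1, outside that list, fell too (-5.56 ± 0.36). Adm (2.00 ± 0.37), the mitophagy receptor Bnip3 (1.20 ± 0.24), Mxi1 (1.16 ± 0.27) and Ankrd37 (1.08 ± 0.22) rose, 4 of 21 hypoxia genes (6 over the list alone; adjusted p = 0.464 with an estimated correlation), next to Fn1 (1.44 ± 0.18), the signalling regulator Rgs2 (1.21 ± 0.23) and Sox11 (1.12 ± 0.26). Of the G2/M genes 7 of 24 fell (17 over the list alone; adjusted p = 0.464 with an estimated correlation), and of the S phase genes 3 of 21 (8 over the list alone; adjusted p = 0.464 with an estimated correlation). In total 38 genes rose and 147 fell of 10663, a count that was 315 without tumour 5, 108 by DESeq2, 38 on thinned sums and 0 in the joint fit.

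State 7 (1281 cells, median pseudotime 26.9, 7 tumours) held 4 higher and 30 lower genes of 11420. G2/M genes fell in 11 of 24 (20 over the list alone), for example Ube2c (-2.22 ± 0.31, adjusted p = 0.0173), Ccna2 (-2.001 ± 0.26), Cdk1 (-1.98 ± 0.31) and Birc5 (-1.87 ± 0.25). The list had adjusted p = 0.185 with an estimated correlation. S phase genes fell in 1 of 22 (8 over the list alone; adjusted p = 0.332 with an estimated correlation). Immediate early genes ranked higher, with a mean of 0.27 and 0 called, also over the list alone (adjusted p = 5.22e-05; adjusted p = 0.344 with an estimated correlation). The calcium-binding protein S100g (1.69 ± 0.29) and Mxd1 (1.13 ± 0.21), an antagonist of Myc, rose in all 7 tumours. The count moved to 179 without tumour 2, 6 without tumour 3, 11 without tumour 5, 14 without tumour 7 and 10 without tumour 8, and was 1 in batch CT01, 703 in batch CT02 and 296 by DESeq2, and 288 genes differed between batches by an interaction test.

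In states 8 and 9 no gene passed by edgeR against the other cancer cells, whereas the joint fit of all states called 199 and 316. State 8 (764 cells, 4 tumours of batch CT01) had 0 genes called by edgeR, 693 of 13149 at an unadjusted p under 0.05 where 657 are expected by chance, and 35 by DESeq2. State 9 (2360 cells, 6 tumours) had 0 called by edgeR, 951 of 12224 at an unadjusted p under 0.05 where 611 are expected by chance, and 18 by DESeq2. In state 9 edgeR called 3 genes without tumour 1 and 1 without tumour 8. Gene lists still ranked apart at the preset correlation. In state 8 the matrix list had a median log2 fold change of -1.11 (adjusted p = 1.61e-13; adjusted p = 0.456 with an estimated correlation) and the epithelial junction list of 1.14 (adjusted p = 9.68e-13; adjusted p = 0.483 with an estimated correlation), with 5 and 0 members called when adjusted over the list alone and 0 over all genes. In state 9 the classical list had a median of -1.20 (adjusted p = 2.38e-15; adjusted p = 0.456 with an estimated correlation), with 9 of 24 members called over the list alone and 0 over all genes. Mitochondrially encoded genes, a sign of RNA quality, ranked lower in both states. Their mean was -0.43 in state 8 (adjusted p = 0.000243; adjusted p = 0.623 with an estimated correlation) and -0.36 in state 9 (adjusted p = 2.38e-05; adjusted p = 0.560 with an estimated correlation). Immediate early genes had a mean of -0.25 in state 8 (adjusted p = 0.0414; adjusted p = 0.734 with an estimated correlation) and 0.14 in state 9 (adjusted p = 0.00807; adjusted p = 0.549 with an estimated correlation). No member of either list was called, also over the list alone.

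Pseudotime orders the cells of all tumours on one scale, so the change along it was taken inside each tumour. Over 7 tumours with enough bins (tumour 6 had too few), 15 of 29 lists rose and 0 fell against a slope of 0, each rising in 7 of 7 tumours with p = 0.0156, the smallest the exact sign-flip test allows, and adjusted p = 0.0302. Bins weighed the same whatever their size. The first bin held only 24, 31, 40 and 28 cells in tumours 1 to 4, and the second bin of tumour 1 held 20. Immediate early genes had the steepest slope, 0.482 ± 0.224 log2 units per bin (SD, n = 7), and 18 of its 22 members were above 0 in all 7 tumours, for example Klf6 (0.853 ± 0.483), a zinc finger factor induced by injury, and the phosphatase Dusp1 (0.661 ± 0.256). These genes also respond to tissue dissociation. TGF-beta response genes rose by 0.346 ± 0.167, with Rhob at 0.741 ± 0.295 and Skil at 0.674 ± 0.313, MAPK output genes by 0.344 ± 0.155, with Ier3 at 0.587 ± 0.276 and Spry2 at 0.574 ± 0.263, and the laminin and integrin list by 0.323 ± 0.105, with Itga6 at 0.473 ± 0.268. Hypoxia genes rose by 0.260 ± 0.105, with the stress-induced Ndrg1 at 0.563 ± 0.124 and the angiogenic factor Vegfa at 0.479 ± 0.105.

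The other lists past the threshold were YAP and TEAD targets (0.274 ± 0.0955), lysosome (0.224 ± 0.0776), unfolded protein response (0.211 ± 0.0816), p53 targets (0.207 ± 0.0992), tumour cytokines (0.185 ± 0.127), matrix (0.184 ± 0.0425), glycolysis (0.179 ± 0.133), cholesterol synthesis (0.157 ± 0.123), mesenchymal adhesion (0.122 ± 0.109) and basal-like genes (0.0852 ± 0.0672). Oxidative phosphorylation had a slope of -0.0748 ± 0.0504, below 0 in 6 of 7 tumours, and did not pass (exact adjusted p = 0.0566). The classical list was mixed: its slope was -0.0681 ± 0.106 (exact adjusted p = 0.215), with Gkn1 at -0.589 ± 0.398 and Gkn3 at -0.416 ± 0.281 below 0 in all 7 tumours and Onecut2 (0.584 ± 0.221) above 0 in all 7. G2/M (-0.00447 ± 0.139) and S phase (0.0238 ± 0.0928) showed no common direction against 0. The median slope of all 7388 genes tested for it was 0.183, and 4 of the 15 lists past the threshold lay below it (glycolysis, cholesterol synthesis, mesenchymal adhesion and basal-like). Against 10000 random lists of like expression, 8 of the 29 lists lay below the central 95%. Among these were G2/M (random range 0.106 to 0.216), S phase (0.115 to 0.217), classical (0.0264 to 0.160), acinar (0.0594 to 0.160) and oxidative phosphorylation (-0.0134 to 0.173). Mean slopes of the immediate early list were 0.630 over the 4 tumours of batch CT01 and 0.284 over 3 of batch CT02, and for hypoxia 0.253 and 0.269. With bins drawn within each tumour, which span other stretches of pseudotime, 0 lists passed. The slopes there were 0.126 for immediate early, 0.1002 for TGF-beta response, 0.0929 for MAPK output and 0.0958 for hypoxia genes. None passed with any 1 of the 7 tumours left out, where the smallest p the exact test allows is larger, which all but fixes this outcome after adjustment.

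**Figure D4:**
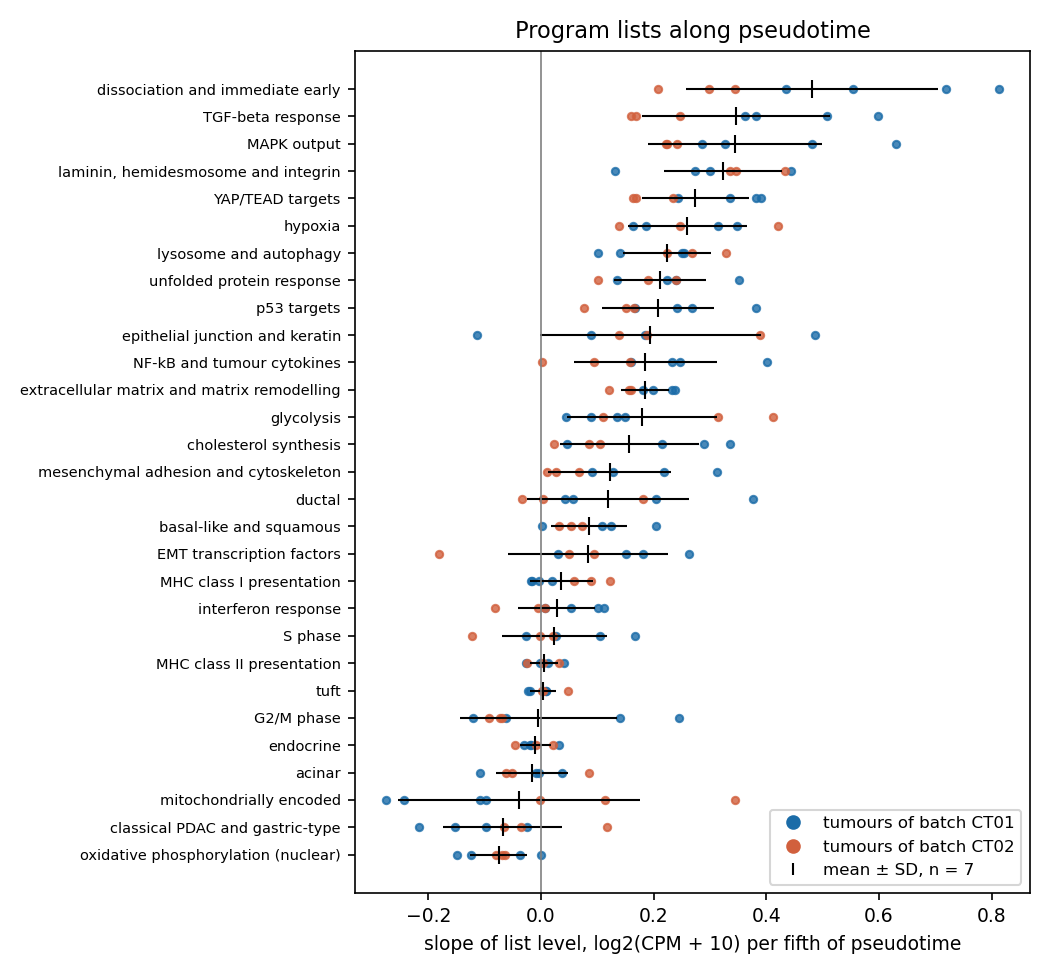
Slope of list level along pseudotime bins (x axis, log2 units per bin) for the 29 gene lists (y axis), with 1 point per tumour and the mean with a bar of 1 SD over 7 tumours. The immediate early list is steepest at 0.482 and oxidative phosphorylation lowest at -0.0748.

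Across the 8 tumours, 2 of 9 relations between list levels passed the exact pairing permutation test. Epithelial junction and classical gene levels varied together (Pearson r = 0.869, exact p = 0.00521, adjusted p = 0.0329; Spearman rho = 0.857, exact p = 0.0107, adjusted p = 0.0482), as did classical and basal-like levels (r = 0.853, exact p = 0.00732, adjusted p = 0.0329; rho = 0.857, exact p = 0.0107, adjusted p = 0.0482). Without tumours 2 and 4, farthest from the median epithelial level, the first was r = 0.7098 (exact p = 0.0903, adjusted p = 0.406) and no longer passed. Without tumours 2 and 8 the second was r = 0.860 (exact p = 0.0264, adjusted p = 0.238) and no longer passed after adjustment. Hypoxia and glycolysis levels gave r = 0.791 (exact p = 0.0173, adjusted p = 0.0519) and rho = 0.381 (exact p = 0.360), a relation that rested on tumours 6 and 7, as r was -0.0406 without them. Epithelial level gave r = -0.701 with mesenchymal adhesion (exact p = 0.0525), -0.528 with transition factors, -0.385 with matrix, 0.613 with MHC class I and -0.528 with G2/M, and MHC class I gave 0.465 with interferon response, none of which passed (exact adjusted p from 0.118 to 0.348). Spearman rho of these 6 ran from -0.762 (epithelial with G2/M, exact p = 0.0368, adjusted p = 0.110) to 0.524, and r without the 2 farthest tumours from -0.514 to 0.0426, turning to -0.385 for MHC class I. Both batches hold 4 tumours, too few for a correlation within either. With levels centred within batch and pairings permuted within batches, 0 of 9 relations passed. Epithelial with classical then had r = 0.864 (exact p = 0.0156, adjusted p = 0.120) and rho = 0.900 (exact p = 0.0243, adjusted p = 0.109). Classical with basal-like had r = 0.849 (exact p = 0.0295, adjusted p = 0.120) and rho = 0.900 (exact p = 0.0243, adjusted p = 0.109).

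Between tumours, the median SD of log2 CPM over 9112 genes was 0.655 (n = 8). The 10 genes of largest spread were Crabp1, Pdyn, Slc17a1, Crisp1, Tff3, Sprr2e, Ins1, Igf2bp1, Fabp1 and Lrp2, with SDs from 3.71 to 4.21. Values at 0 counts rest on the added 0.5 counts, and 1 of the 10 kept its place with no minimum and log2(CPM + 10). Fabp1, a fatty acid binding protein of liver and gut, reached 1329 CPM in tumour 6, 67.2 CPM in tumour 4 and 3.96 CPM or less elsewhere. Igf2bp1, an oncofetal RNA-binding protein, was at 61.1 CPM in tumour 1 and 27.5 in tumour 7 but at 3.58 or less in the rest. Crisp1 was at 11.8 to 32.3 CPM in 6 tumours and below 0.1 in tumours 2 and 7. Ins1, an insulin gene of endocrine cells, ranged from 0 in tumour 7, which had no endocrine-like cells, to 37.9 CPM in tumour 2, which had the highest endocrine-like share (0.616%). The lists of largest spread were classical and gastric-type (SD 0.872), epithelial junction (0.662) and acinar (0.652), the last highest in tumour 6, where acinar-like cells were most frequent.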

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

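The test of transcript length between the batches was chosen after the result it measures had been seen, and the patterns weighed here were picked because they stood out in these data. Of 67 values compared over the tumours, 5 had 1 tumour far from the others, where about 1 in 20 such groups, or 3.35, would do so by chance. Among the 67 were 15 pseudotime slopes over 7 tumours and the 10 genes of largest spread between tumours. Those 10 were chosen for their spread, so the chance rate does not hold for them, and 3.35 is only a rough guide. Tumour 6 held 13.3% acinar-like barcodes, with the next tumour at 3.89%. Tumour 5 held 25.1% mesothelial-like barcodes, with the next at 4.11%. The MAPK output list stood at a level of 5.21 in tumour 6 against 5.87 in the nearest tumour, and the interferon response list at 4.28 in tumour 4 against 3.99. Tff3 had 0 counts in tumour 3, so its log2 CPM of -6.46 is set by the added 0.5 counts, and the next lowest tumour was at 2.65. By interaction tests in edgeR, the contrast differed between batches CT01 and CT02 for 472 genes in state 1, 549 in state 4 and 288 in state 7. Outside the annotated cancer cells, Cd74 was detected in 86.2% of a mesothelial-like cluster and in 2.52% of the cancer cells.

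The first pattern is that median pseudotime of all 4 tumours of batch CT01 lay above that of all 4 of batch CT02. A difference in depth is argued against as its whole source, since among cells of 6000 to 9000 UMIs the gap was 29.2 against 31.0 over all cells, or 94.0% of it. Matching cells after the ordering was made does not remove depth from the ordering itself. Inside tumours, UMI count and pseudotime had a Spearman rho of 0.341 to 0.586 in tumours 1 to 4. In tumours 5 to 8 it ran from -0.386 to -0.0462. A processing difference that acts on every cell type may contribute. The batch difference of cancer cells correlated across genes with that of fibroblast-like cells at r = 0.872, the highest of 35 splits. It covered 3 tumours of batch CT01 and 4 of CT02, without tumour 3, which had 2 fibroblast-like cells. The other splits ran from 0.358 to 0.824 (median 0.548), so a high r is not particular to the batch split. Free RNA of cancer cells in other droplets is not excluded either. Over 400 genes at 2 or more times the level in that class, r was 0.699 (highest other 0.666). A transcript-length bias stays undecided, with a Spearman rho of 0.391 in fibroblast-like cells but 0.112 in cancer cells. The former covers 1992 genes over 7 tumours and the latter 7059 genes over 8. The 2 values therefore differ in genes and tumours as well as in class. Differences between the mice remain open as well, and no biological explanation was tested because the labels give 1 group.

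The second pattern is that 15 lists rose along pseudotime within tumours and 0 fell. Depth was not tested as a source of it, although UMI counts rose with pseudotime inside tumours 1 to 4, and not inside tumours 5 to 8. A transcript-length bias may contribute, as gene slopes correlated with transcript length in each of the 7 tumours (median rho 0.327, from 0.234 to 0.437). A shift shared by genes of like expression is undecided for the 15 lists as a set. Of them 7 lay inside the central 95% of random lists of like expression, and the others lay above it. These ran from immediate early (0.482, random range -0.0302 to 0.147) to lysosome (0.224, random range 0.0533 to 0.213). A lower share of nuclear-retained RNA early in pseudotime also stays open. The slopes of Neat1 (0.782), Meg3 (0.755) and Kcnq1ot1 (0.430) were above 0 in 7 of 7 tumours. That of Malat1 (0.257) was above 0 in 5 and that of Miat (0.00148) in 2. In the first bins of tumours 1 to 4, of 24, 31, 40 and 28 cells, median Malat1 was 0, 489, 205 and 4116 CPM. In the later bins of these tumours it was 6880 CPM or more. Among cells at or above the median level of Malat1, the lists' median slope was 96.3% of its value over all cells. That filter took out the first bin of all 4 tumours of batch CT01, so it cannot decide the question. No biological explanation was tested.

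The third pattern is that the contrast of state 4 differed between batches for 549 genes. A comparison arm that lies on opposite sides of state 4 in the batches is a candidate explanation. Against state 7 alone, the batches' fold changes correlated across 3219 genes at r = 0.5675, against 0.225 for the contrast with all other cancer cells. The former used 4 tumours of batch CT01 and 3 of batch CT02, the latter 4 of each. Tumour 6, with 4 cells of state 7, did not enter the former, so the 2 values differ in tumours as well as in arm. A transcript-length bias may contribute too, with a rho of -0.457 between transcript length and the difference between batches. No biological explanation was tested.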

How the results depend on the processing

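Among the alternative settings, the contrasts without cells lacking a state, within each batch, and of states held by 3 tumours, and the relations with levels centred within batch, were chosen after the data had been seen. Of the values under other settings, 327 of the main values stayed on the same side of their threshold or within their allowed range, 51 moved, 50 weakened and 2 grew stronger. Named genes kept direction and call in 2273 comparisons, lost the call in 564 and turned in 4. Other normalization (RLE) left 168 named genes as called and 4 not, and DESeq2 163 and 9. The causes were not tested unless stated.

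Counts of genes called moved by over 1.5 times as follows. Without the replicate block they were 0 in states 1, 4, 7 and 13, 1 in state 3 and 140 in state 12, since differences between tumours then enter the spread. Without a fold minimum they were 2583 in state 1, 290 in state 3 and 514 in state 4. DESeq2 called 108 in state 3, 296 in state 7, 35 in state 8 and 18 in state 9. Without a low-count filter, state 3 had 375 and state 7 had 69. On thinned sums, state 3 had 38, state 7 had 5 and state 12 had 1042. The joint fit, whose comparison arm is another, gave 0 in state 3, 580 in state 4, 529 in state 7, 199 in state 8, 316 in state 9 and 471 in state 13. State 7 had 20 without cells over 10% mitochondrial UMIs, 19 without cells lacking a state and 5 with at least 50 cells. State 9 had 2 with at least 10 cells and 2 without cells over 10% mitochondrial UMIs. In batch CT01 alone, state 7 had 1, state 9 had 1 and state 12 had 35. In batch CT02 alone, state 4 had 560, state 7 had 703 and state 12 had 0. The tests within a batch hold fewer tumours.

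Leaving out each tumour gave ranges of 938 to 1455 genes in state 1, 137 to 315 in state 3, 106 to 377 in state 4, 6 to 179 in state 7, 0 to 0 in state 8, 0 to 3 in state 9, 170 to 2238 in state 12 and 185 to 254 in state 13. Tumours that moved a count by over 1.5 times were tumour 5 in state 3 (315 without it), tumours 3, 7 and 8 in state 4 (162, 106 and 156), tumours 2, 3, 5, 7 and 8 in state 7 (179, 6, 11, 14 and 10), tumours 1 and 8 in state 9 (3 and 1) and tumours 4, 7 and 8 in state 12 (301, 235 and 170). The number of lists past the threshold ranged over 12 to 15 in state 1, 12 to 16 in state 3, 10 to 15 in state 4, 11 to 14 in state 7, 15 to 18 in state 8, 13 to 14 in state 9, 11 to 13 in state 12 and 13 to 16 in state 13. With an estimated correlation 0 lists passed in each of the 8 states. With fry, 2 passed in state 1, 1 in state 3, 4 in state 4, 3 in state 7, 1 in state 8, 0 in state 9, 2 in state 12 and 0 in state 13.

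Signs turned for Acta2 in state 1 without the replicate block (-0.49) and for Gkn3 (1.36), Muc6 (0.78) and Muc5ac (0.86) of state 13 in the joint fit, none past the threshold there. With bins drawn within each tumour 0 lists passed along pseudotime. Leaving out tumours gave 0 to 0, an outcome that the larger smallest p of that test all but fixes, so it tells nothing about single tumours. Of the relations, 0 passed with log2(CPM + 1), where epithelial with classical had r = 0.866 and classical with basal-like r = 0.775, and 0 passed without the 2 farthest tumours (0.7098 and 0.860) and with levels centred within batch (0.864 and 0.849). Hypoxia with glycolysis passed on means of per-cell CPM (r = 0.789) and without tumour 8 (0.866). Leaving out each tumour gave 0 to 3 relations. Pearson r ranged over 0.719 to 0.909 for epithelial with classical, 0.668 to 0.922 for classical with basal-like, 0.631 to 0.866 for hypoxia with glycolysis, -0.654 to -0.346 for epithelial with transition factors, -0.846 to -0.321 with mesenchymal adhesion, -0.579 to -0.142 with matrix, 0.348 to 0.817 with MHC class I, -0.662 to -0.328 with G2/M and 0.140 to 0.620 for MHC class I with interferon response. Mean shares ranged over 80.6 to 87.1% for cancer cells, 1.10 to 2.97% acinar-like, 1.94 to 5.44% mesothelial-like, 2.37 to 3.93% fibroblast-like, 0.189 to 0.277% endocrine-like and 5.503 to 6.79% unnamed. The unnamed share was 2.47% among barcodes under 10% mitochondrial UMIs. The median SD between tumours ranged over 0.621 to 0.676 and was 0.126 with no minimum and log2(CPM + 10), changed together.

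Arms of few cells limit the depth, the smallest holding 170205 UMIs in state 1 of tumour 1. Contrasts of cancer cells with other annotated classes were not run, as the annotation holds cancer cells only.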

Other observations

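The values in this part were chosen after the data had been seen, except the exchanges of arms. The mesothelial-like barcodes fell in different clusters by tumour. A cluster of 354 barcodes had Cd74, the invariant chain of MHC class II, in 86.2% of barcodes, H2-Eb1 in 68.6% and H2-Ab1 in 66.4%, at a median of 7341.5 UMIs. Another of 1094 barcodes, 937 of them from tumour 5, had Cd74 in 57.5%, the acute phase gene Saa3 in 97.1% and the protease inhibitor Slpi in 98.8%. Saa3 and Slpi were found in 48.3% and 89.0% of the first cluster. Cd74 was found in 2.70% of the larger and 14.9% of the smaller fibroblast-like cluster, where H2-Ab1 was in 43.1%, in 40.5% of an unnamed cluster of 336 barcodes, and in 2.52% of cancer cells, whose median depth was 9238 UMIs.

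Acinar-like barcodes formed 2 clusters, of 526 and 226 barcodes, and the top 10 genes of the latter by fold included the regenerating genes Reg1, Reg3b and Reg3g, which acinar cells raise on injury. The latter also had Krt19 in 79.2% and Epcam in 51.8% of barcodes, against 26.2% and 32.7% in the former. In cancer cells they were found in 83.2% and 50.4%. Whether these barcodes were acinar cells, other epithelial cells or droplets of 2 cells was not tested. A cluster of 41 barcodes with no name had the adipocyte genes Adipoq in 92.7% and Fabp4 in 95.1%. A cluster of 57 barcodes had the myeloid genes Tyrobp, S100a8 and Lyz2 among its top 10 by fold of the mean, which few barcodes can set. It had Ptprc in 5.26% of barcodes and Krt8 and Krt18 each in 50.9%, at a median of 263 genes. Its median mitochondrial share was 90.9% and it took no name.

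States 6, 10 and 11 were held by 3 tumours each and were compared in an added step. By edgeR 8 genes were called in state 6, all lower, 267 in state 10 (9 higher, 258 lower) and 431 in state 11 (45 higher, 386 lower).

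To ask whether a random choice of arms gives as many genes, the state and the comparison arm were exchanged within tumours. The states were derived by the authors from these same expression values on one scale for all tumours, so cells of a state share a direction by construction, and the exchanges do not show whether chance can be excluded for any state. In state 1, 1286 genes were called and the highest other of 32 exchanges gave 903, from exchanging tumour 1 alone, 1 of 2 tumours of batch CT01 in that contrast. State 4 had 266 (highest other 5) and state 7 had 34 (highest other 1), each with 1 of 50 exchanges drawn as large. For states 8 and 9 the real count is 0 by edgeR (693 and 951 genes at an unadjusted p under 0.05, 35 and 18 by DESeq2), and so all 8 and all 32 exchanges, with 0 genes at most, are as large. States 3, 8, 12 and 13 have too few exchanges for a share under 0.05. In states 3, 12 and 13 the real counts and highest others were 185 and 0, 1640 and 0, and 223 and 170, the last from exchanging tumour 2 alone, the 1 tumour of batch CT01 in that contrast.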
